A study of Mus musculus with 12 samples.

How the data were processed

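The deposited data hold 4 gene expression libraries, 4 B-cell receptor libraries and 4 T-cell receptor libraries from mouse meninges, 2 naive and 2 HI pools of each kind. Per the labels, each library pooled 12 mice and was made with the 10x Genomics 5' kit. Per the series' design text, the libraries came from 2 runs that each held an HI and a naive pool, and the labels do not tie a library's number to a run. Nothing else says how the pools relate beyond each library pooling 12 mice. The p-values of single genes and of shares therefore measure only the spread between these libraries, with any spread between runs inside it. The deposited gene expression values are whole-number UMI counts per gene and barcode, 1 matrix per library with no normalization. The deposited receptor values are UMI and read counts per assembled contig, with the chain, the V, J and C genes and the third complementarity region of each. Per the submitters' processing notes, Cell Ranger 2.2.0 and Seurat were used with the builds mm10 and GRCm38, and which step used which is not stated. The files held only filtered contigs and called barcodes.

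The matrices had 28694 gene rows, of which 28341 IDs matched the gene table, and 58 symbols were used more than once. Symbols are those paired with the IDs in the files, and genes near-identical to others (such as Mt1 and Mt2, or Ccl3 and Ccl4) share reads in ways the deposited counts cannot show. Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept: 5122, 4212, 5945 and 6410 in naive 1, HI 1, naive 2 and HI 2. The lowest UMI total of a barcode was 3629, 3633, 3414 and 3263, the lowest number of genes 814, 794, 926 and 783, and the median mitochondrial share was 2.63%, 2.43%, 2.62% and 2.41%. Doublets were scored with Scrublet (scanpy 1.11.5) per library, and the highest scores were removed at an expected share of 0.8% per 1000 barcodes, which took 210, 142, 283 and 329 cells. This rank was chosen after seeing the data, since the automatic thresholds called 1, 3, 1 and 1 cells. Cells of all libraries were scaled to log counts, and 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9) gave 37 clusters, with seed 1 and no integration of libraries.

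Clusters were named by 38 marker lists fixed before the data were examined: a name needs at least 3 markers detected in at least 20% of cells, a scaled level of at least 0.5 and a score of at least 0.5. Clusters are described by their 10 leading genes by fold among genes detected in at least 25% of cells, with a CPM prior of 5. No name was given where a list of another lineage scored at least 0.65 or where the leading genes held more markers of another list, and clusters with a median doublet score above 0.2 were left out (2 clusters); both thresholds and the grouping of lists into lineages were chosen after seeing the data. They kept clusters 9, 17 and 35 out of BAM. Marker types follow general knowledge of mouse leukocytes and each name stands for cells like that type.

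The unit of testing was the library. Counts were summed per library and class for classes with at least 40 cells in every library (at most 8 classes), which left 6, with 2896 BAM, 520 microglia, 182 non-classical monocytes, 58 cells of cluster 17, 52 classical monocytes and 42 cells of cluster 21 in the smallest library. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr and TMM, HI against naive, 2-sided, with Benjamini-Hochberg adjustment per class at 0.05. DESeq2 1.42.0 was the other tool. Means and SDs are of CPM per library on these sums, n = 2. Shares were tested with edgeR on cells per class with all kept cells of the library as offset. Gene lists, 25 in all and fixed before the data were examined, were tested with camera (limma 3.58.1) on log2 CPM with a prior of 2 and a preset correlation of 0.01, for lists with at least 5 measured genes, adjusted over lists and classes. Differences between classes were tested in edgeR as the interaction of class and HI with a term per library, for the 6 pairs of the 4 largest tested classes. List tests of these differences were added after seeing the data. edgeR draws each gene's spread towards that of all genes. Very small p-values of the interaction therefore do not measure each gene's own spread between libraries. The camera p-values with the preset correlation compare the genes of a list with all other genes. They rest largely on the number of genes and do not by themselves measure the spread between libraries. For a gene with 0 UMIs in a group, the fold is a lower bound against 3 counts over the summed group, and with 1 to 3 UMIs the ratio is given with its interval.

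Genes are named by a rule set before the data were examined: genes past 0.05 with both HI libraries beyond both naive libraries, in order of fold change, up to 12 each way in the 2 classes with most calls, 4 each way in the other classes and 5 each way over all cells. Gene models without a name, receptor segments and sex-linked genes were left out. Up to 4 measured members with the smallest p of each described list were added. Other members of lists, the levels in neutrophils and the cluster make-up of BAM were chosen after their values were seen. Values of some genes that meet the rule are not reported here.

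Receptor contigs were used where productive and where the barcode was a kept cell of the gene expression library with the same description. A clone was at least 2 cells with an identical nucleotide sequence of the third complementarity region and the same V and J genes. The median productive contig had 64, 68, 60 and 52 UMIs in B-cell libraries and 17, 16, 12.5 and 11 in T-cell libraries of naive 1, HI 1, naive 2 and HI 2. Shares of single libraries carry 95% Clopper-Pearson intervals, and a share of 0 carries the limit of 3 counts; intervals and limits cover counting error only.

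The gene tests, and the interaction for 1 pair of classes, were tested on simulated data with 200 changed genes drawn on the real means and depths. The list test had 1 shifted list, and the share test had changed classes in repeated draws. Each gene was drawn with the spread that edgeR's trend gives at its level, and all classes with 1 common spread. No gene had a spread of its own and no spread between runs was added, so these recoveries are a best case. In BAM (12707 genes) 89.9% of 2-fold and 99% of 4-fold changes were recovered with 5 false calls. In microglia (10856 genes) 84.8% and 98.0% were recovered, in non-classical monocytes (8363) 72.4% and 96.0%, in cluster 17 (6581) 66.3% and 98.0%, in classical monocytes (6582) 31.6% and 93.6%, in cluster 21 (6249) 25.5% and 84.8% and over all cells (14500) 71.7% and 91.8%. False calls numbered 9, 6, 13, 6, 5 and 5. For the interaction of BAM and non-classical monocytes (8415 genes) 67% and 92% were recovered with 7 false calls, and of 4-fold changes in shares 50% were recovered (75 of 150, 2 false calls). The 1 shifted list was called with 0 false calls. The simulated genes were drawn independently of each other, so this does not show how the list test behaves where genes move together. In the data no list call held with an estimated correlation. That test rests on the few residual degrees of freedom that these libraries leave, so hardly any list could pass it after adjustment. In BAM the hypoxia list had an estimated correlation of −0.0315, below the preset 0.01, yet its unadjusted camera p went from 3.97e-15 to 0.0130. The lost calls therefore do not show that genes moved together, nor do they bear out the preset calls.

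Alternatives fixed before the data were examined were another resolution (0.8, giving 32 clusters), doublets kept, a stricter cell filter (500 genes, 5% mitochondrial), RLE size factors, no filter on low counts, DESeq2, the replicate number as a block, TMM over classes for shares, an estimated correlation, fry, at least 2 UMIs per contig, all productive contigs, the clonotypes of the files, and each library left out in turn. BAM with clusters 9, 17 and 35 was added after seeing the data. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9) and R 4.3.3 were used.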

Results

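The data describe leukocytes of the meninges, the membranes around the brain, in C57Bl/6j mice at postnatal day 4. They were profiled as single cells by 5' gene expression sequencing with paired sequencing of B-cell and T-cell receptors. Animals were either naive or taken 6 h after hypoxia-ischemia (HI), a model of brain injury at birth in which blood flow and oxygen are both reduced. The samples hold no sham group. Any surgery, anaesthesia or handling that came with HI therefore cannot be told apart from HI itself. Each gene expression library pooled 12 pups, 6 male and 6 female, and there were 2 naive and 2 HI libraries, each with its own B-cell and T-cell receptor library, 12 libraries in all. Naive 1 held 5134 barcodes and 62062630 UMIs, HI 1 held 4213 barcodes and 51986763 UMIs, naive 2 held 5954 barcodes and 65759672 UMIs, and HI 2 held 6421 barcodes and 68543046 UMIs. After filtering and removal of doublets, 4912, 4070, 5662 and 6081 cells remained in the same order, with medians of 10800.5, 11091, 9928 and 9536 UMIs per cell.

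The first question was which leukocytes the neonatal meninges hold. Border-associated macrophages (BAM), the resident macrophages of the brain's coverings, made up 63.9% ± 4.47 (SD, n = 2) of the kept cells of naive libraries. Microglia-like cells made up 11.6% ± 3.13, and non-classical monocytes, which patrol the vessel wall and carry Ace and Treml4, made up 6.74% ± 1.24. Classical monocytes, the Ly6c2 and Ccr2 positive cells recruited in inflammation, made up 1.49% ± 0.403. B cells (1.09% ± 0.0693) and pre-B cells with the surrogate light chain gene Igll1 (0.515% ± 0.0954) were both present. So were mature neutrophils (0.547% ± 0.226), immature neutrophils with the granule genes Camp and Ltf (0.397% ± 0.188), group 2 innate lymphoid cells (0.232% ± 0.104) and fibroblasts (0.134% ± 0.0402). Each class name stands for cells that resemble that type by markers fixed in advance.

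Other clusters matched no single marker list, or mixed several, and are named by number with their leading genes. Cluster 9 (7.42% ± 1.17 of naive cells) carried BAM markers together with the neuronal and glial genes Tubb3, Stmn2 and Fabp7. Cluster 35 (0.310% ± 0.0357) carried BAM markers together with Ttr, Sostdc1 and Folr1, genes of the choroid plexus epithelium. Cluster 17 (1.68% ± 0.931) shared markers of BAM and microglia and led with Cxcl16, Ccl12 and Axl. Cluster 21 (1.17% ± 0.124) led with Cd209a and H2-Eb1, genes of dendritic cells. Among small clusters, 25 held T and NK cell genes (Cd3d, Nkg7; 0.861% ± 0.193) and 29 held Tcrg-C1 and Il7r (0.379% ± 0.0113). Cluster 31 led with Cpa3 and Mcpt8 (0.483% ± 0.00830), 32 with Cd163l1 and Trdv4 (0.418% ± 0.0420) and 33 with the dendritic cell gene Clec9a (0.336% ± 0.101).

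HI was then compared with naive for the make-up of the cells. Mature neutrophils, the first cells that blood sends to injured tissue, rose. Macrophages carrying neuronal RNA and macrophages carrying choroid plexus RNA fell. BAM, microglia and both kinds of monocytes kept shares that the test did not separate. Of 19 classes tested with edgeR, 1 rose and 2 fell, and 6 had an unadjusted p under 0.05. Mature neutrophils went from 0.547% ± 0.226 to 1.92% ± 0.302 (SD, n = 2 each), 3.52-fold higher (log2 change 1.80, edgeR adjusted p = 0.0416). Cluster 9 went from 7.42% ± 1.17 to 0.994% ± 0.432, 7.46-fold lower (log2 change −2.88, edgeR adjusted p = 0.0153). Cluster 35 held 33 naive cells and 1 HI cell, a ratio of 0.0316 (Clopper-Pearson interval 7.76e-04 to 0.189, edgeR adjusted p = 0.0162), and the 0 of 6081 cells in HI 2 allow a share of up to 0.0493%. The genes that set clusters 9 and 35 apart, among them Fabp7 and Ttr, themselves fell in BAM, so these cell counts and those gene levels are 1 observation. With 2 libraries per group an exact 2-sided permutation test cannot give a p below 0.33. With TMM over classes in place of all kept cells as the scale no class passed (edgeR adjusted p of 0.181 for mature neutrophils, 0.0607 for cluster 9 and 0.0910 for cluster 35). With the stricter cell filter mature neutrophils did not pass (edgeR adjusted p = 0.0556). Without naive 1 or without naive 2 no class passed (adjusted p of 0.302 and 0.233 for each of the 3), and without HI 2 there were 6 classes that passed.

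**Figure D1:**
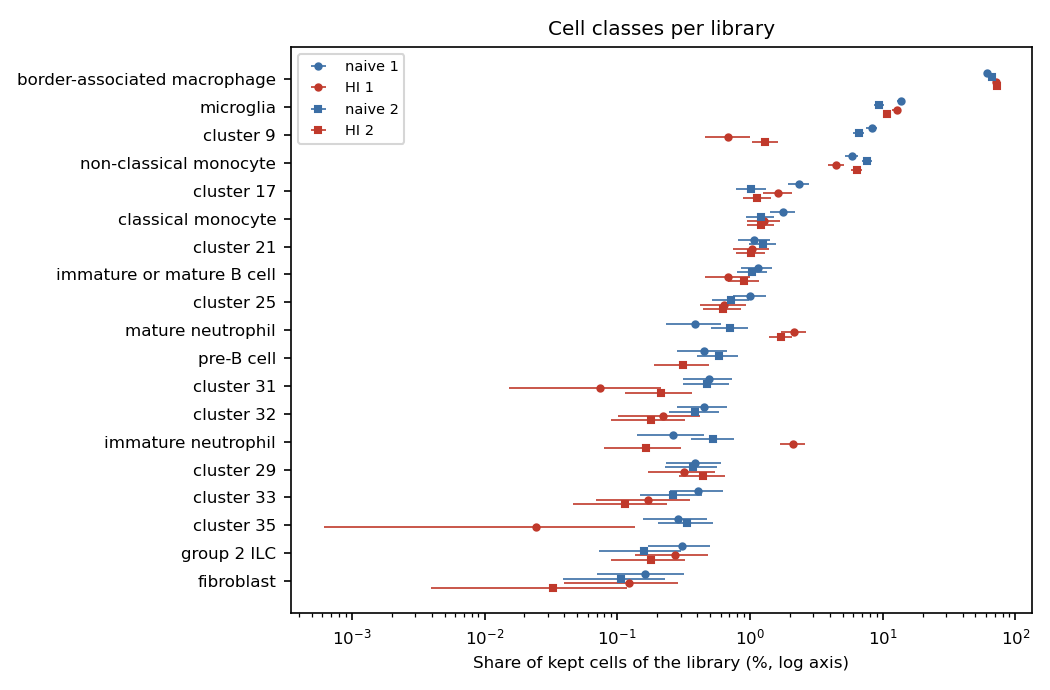
Share of kept cells (%, log axis) of each class in each library, with 95% Clopper-Pearson intervals, naive and HI. Mature neutrophils lie higher and cluster 9 lower in both HI libraries than in both naive ones; shares of 0 (pre-B cells in HI 1 and cluster 35 in HI 2) cannot be drawn on a log axis.

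Other shares did not pass. BAM went from 63.9% ± 4.47 to 72.2% ± 1.501 (SD, n = 2 each; edgeR adjusted p = 0.716), microglia from 11.6% ± 3.13 to 11.8% ± 1.43 (0.959), non-classical monocytes from 6.74% ± 1.24 to 5.42% ± 1.34 (0.676) and classical monocytes from 1.49% ± 0.403 to 1.25% ± 0.0429 (0.716). The Cpa3 and Mcpt8 cluster 31 went from 0.483% ± 0.00830 to 0.144% ± 0.0990 (edgeR unadjusted p = 0.0228, adjusted p = 0.108). Clusters 32 and 33 went to 0.201% ± 0.0285 and 0.144% ± 0.0402 (edgeR adjusted p = 0.139 for each). B cells went to 0.796% ± 0.153 (edgeR adjusted p = 0.479). The pair of HI libraries did not resemble each other in their immature cells. Immature neutrophils were 2.11% of HI 1 (Clopper-Pearson interval 1.69 to 2.60) and 0.164% of HI 2 (0.0789 to 0.302), and their log2 change of 1.47 (edgeR adjusted p = 0.479) became −1.28 without HI 1 and 2.39, past the threshold, without HI 2. Pre-B cells were 0 of 4070 cells in HI 1, which allows up to 0.0737%, and 0.312% of HI 2 (0.188 to 0.487).

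Resident macrophages were compared first for gene expression. In BAM, RNA of Lrg1 and Saa3, secreted acute-phase proteins, rose, with Il1r2, a decoy receptor that traps interleukin-1, and Cxcl10, a chemokine that draws T cells. Lrg1 is also a leading gene of the neutrophil cluster and Il1r2 is on the list of neutrophil RNA, while the neutrophil gene S100a9, at 107966 to 141661 CPM in the neutrophil cluster, went from 0.844 ± 0.752 to 3.65 ± 3.06 CPM in BAM (SD, n = 2 each). Steap4, a metal reductase, Nrg4, a secreted growth factor, and Egln3, the oxygen-sensing hydroxylase that the hypoxia factor HIF itself induces, rose as well. The circadian repressors Nr1d1 and Nr1d2 fell. So did Ttr, the thyroid hormone carrier of the choroid plexus, and genes with neuronal functions such as the postsynaptic scaffold Dlgap3, the synaptic vesicle GTPase Rab3c and the septin Sept3. These 3 were at trace levels, with 30 UMIs in naive and 3 in HI for Dlgap3, 50 and 13 for Rab3c and 85 and 26 for Sept3. Whether they are RNA of BAM or neuronal RNA like that in cluster 9 was not tested. edgeR called 655 of 12844 genes, 367 higher and 288 lower, from 34572700 to 46574300 UMIs per library; DESeq2 called 640, of which 526 were shared. Cells of clusters 0 (Cd209f, Cd163) and 1 (Lyve1, Fcna) made up 32.4% and 23.3% of BAM in naive 1 and 33.2% and 24.8% in naive 2. In HI 1 and HI 2, cluster 0 held 10.7% and 7.56% and cluster 1 held 11.9% and 16.9%. Cluster 2 went from 1.71% and 1.26% in naive 1 and naive 2 to 24.9% and 24.5% in HI 1 and HI 2, and cluster 10 from 0.302% and 0.316% to 14.2% and 5.88%. Changes within BAM were not separated from shifts between these clusters.

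The largest rises in BAM, and several of the largest falls, were in genes of low abundance. Lrg1 went from 0.524 ± 0.263 to 7.48 ± 1.87 CPM (SD, n = 2 each; log2 change 3.89, SE 0.32, edgeR adjusted p = 0.00167), and Saa3 from 0.858 ± 0.837 to 8.43 ± 2.88 CPM (3.35, SE 0.48, adjusted p = 0.0104). Cxcl10 had 12 UMIs in naive and 280 in HI BAM (log2 change 4.49, edgeR adjusted p = 0.00854), and Steap4 had 2 and 49, a ratio of 23.1 (Clopper-Pearson interval 6.07 to 196). Il1r2 rose by 3.13, Egln3 by 3.27, Nrg4 by 3.58, the bicarbonate exchanger Slc4a8 by 4.41, the dynein Dnah2 by 3.62, Ttc39c by 3.34, the transporter Slc16a14 by 3.10 and the interferon-inducible Ifit1bl1 by 3.09 on the log2 scale. Nr1d1 went from 4.22 ± 0.745 to 0.956 ± 0.288 CPM (log2 change −2.09, SE 0.25, edgeR adjusted p = 0.00550) and Nr1d2 from 12.2 ± 2.10 to 3.77 ± 0.0132 CPM (−1.68, SE 0.15, adjusted p = 0.00181). Ttr went from 15.4 ± 5.43 to 3.69 ± 1.70 CPM (log2 change −2.08, edgeR adjusted p = 0.0121) and Rab3c from 0.655 ± 0.0385 to 0.154 ± 0.0548 CPM (−2.00). Dlgap3 had 30 UMIs in naive and 3 in HI, a ratio of 0.0944 (Clopper-Pearson interval 0.0184 to 0.304). Fam81a changed by −2.79, Rimklb by −2.58, the neuronal kinase Mapk10 by −2.25, the meiotic recombinase Dmc1 by −2.09, Sept3 by −1.79, Glb1l2 by −1.62 and the G protein gene Gnal by −1.47 on the log2 scale. Lrg1, Dnah2, Nrg4, Saa3, Ttc39c, Nr1d1, Ttr and Nr1d2 passed without any single library. Of the 24 genes named by the fixed rule, the call ended for 13 without naive 1, 16 without naive 2, 2 without HI 1 (Rimklb −2.76, edgeR adjusted p = 0.0561, and Mapk10 −2.02, 0.0904) and 3 without HI 2 (Rimklb −2.39, 0.0923, Mapk10 −2.60, 0.0537, and Fam81a). The count of calls was 196 without naive 1, 1194 without HI 1, 105 without naive 2 and 1800 without HI 2. Without naive 2 the calls of Cxcl10 (3.81, edgeR adjusted p = 0.0527), Il1r2 (2.80, 0.0751), Egln3 (3.60, 0.0859), Steap4 (4.24, 0.115) and Slc4a8 (3.67, 0.0535) ended, and without naive 1 those of Egln3 (3.02, 0.0593) and Steap4 (4.46, 0.0707).

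Among gene lists of BAM, hypoxia and glycolysis, the unfolded protein response and the glucocorticoid response passed upwards (14 of 23, 8 of 17 and 7 of 20 genes rose) and the cell cycle downwards (10 of 25 fell), all with the preset correlation between genes. With an estimated correlation none of these passed (adjusted p = 0.627 each). Pfkl, Pgam1 and Pdk1 are enzymes that steer sugar through glycolysis, and Slc2a1 is the main glucose transporter. Cd163, the haemoglobin scavenger receptor, Fkbp5, the chaperone of the steroid receptor, and the metallothionein Mt1 are glucocorticoid targets. Mki67, Top2a and Tpx2 mark dividing cells. Nor did any other list call, in any class, hold with an estimated correlation, and each such p follows the call. With so few libraries that test can hardly be passed, so it cannot decide on these lists. Of 23 hypoxia genes 14 rose and 0 fell, and adjusted over the list alone 16 rose (camera adjusted p = 1.11e-13, and adjusted p = 0.627 with an estimated correlation). Pfkl went from 36.2 ± 1.44 to 59.7 ± 0.150 CPM (SD, n = 2 each; log2 change 0.73, edgeR adjusted p = 0.00167), Pgam1 from 144 ± 4.28 to 275 ± 30.4 CPM (0.94), Pdk1 rose by 0.69, Higd1a by 0.54 and Slc2a1 by 1.03. Of 25 cell cycle genes 0 rose and 10 fell, 21 adjusted over the list alone (camera adjusted p = 1.03e-12, and adjusted p = 0.627 with an estimated correlation); Tpx2 changed by −0.53, Mki67 by −0.40 and Top2a by −0.47. Of 17 unfolded protein response genes 8 rose, and adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 1.96e-06, and adjusted p = 0.627 with an estimated correlation), with the chaperones Sdf2l1 at 0.67, Pdia4 at 0.49, Manf at 0.45 and Hspa5 at 0.43. Of 20 glucocorticoid response genes 7 rose and 1, Dusp1, fell (−1.03), against 9 and 2 adjusted over the list alone (camera adjusted p = 7.66e-05, and adjusted p = 0.627 with an estimated correlation). Cd163 went from 282 ± 4.54 to 538 ± 32.9 CPM (log2 change 0.94, edgeR adjusted p = 9.67e-04), Fkbp5 from 3.16 ± 0.448 to 12.7 ± 0.472 CPM (2.02), and Mt1 rose by 1.00 and Mt2 by 1.18.

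In BAM, Socs3, a feedback inhibitor of cytokine signalling, went from 1.62 ± 0.205 to 12.8 ± 3.43 CPM (SD, n = 2 each; log2 change 3.02, SE 0.23, edgeR adjusted p = 0.00157), and the monocyte chemokine Ccl12 from 200 ± 13.4 to 473 ± 78.9 CPM (1.25, adjusted p = 0.00201). With Tnf (0.69), Icam1 (0.61), Ccl7 (0.47) and Cxcl10, 6 of 24 NF-kB genes rose and 0 fell, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.00250, and adjusted p = 0.705 with an estimated correlation). Of 17 phagocyte and lipid genes 4 rose, 5 adjusted over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.762 with an estimated correlation): Spp1 (osteopontin) went from 112 ± 10.5 to 584 ± 186 CPM (log2 change 2.38), Lgals3 rose by 1.34, Abcg1 by 0.77 and Fabp5 by 0.49. Of 24 interferon genes 2 rose, Rsad2 (0.99) and Isg15 (0.40), and adjusted over the list alone 2 rose (camera adjusted p = 0.0370, and adjusted p = 0.918 with an estimated correlation). The BAM homeostatic list did not move as a set (camera adjusted p = 0.774): Cd163, F13a1 (0.53) and Clec10a (0.25) were among 4 that rose, and the phosphatidylserine receptor Timd4 fell (−0.84), and adjusted over the list alone 6 rose and 4 fell of 19. Of 20 microglia homeostatic genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.627 with an estimated correlation). The 13 mitochondrial genes shifted down with 0 called (camera adjusted p = 0.0372, and adjusted p = 0.627 with an estimated correlation). Of 8 neuronal and glial genes 4 fell, 5 adjusted over the list alone (camera adjusted p = 6.97e-06, and adjusted p = 0.627 with an estimated correlation): Fabp7 went from 53.5 ± 1.20 to 24.8 ± 6.55 CPM (log2 change −1.09), Tuba1a changed by −0.69, Stmn2 by −1.02 and Tubb3 by −1.02. Of 5 neutrophil RNA genes Il1r2 rose, 4 adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.627 with an estimated correlation), with S100a8 at 1.79 (edgeR adjusted p = 0.0580) and S100a9 at 2.01 (0.142). Of 9 neutrophil granule genes Prtn3 rose (0.90), 4 adjusted over the list alone (camera adjusted p = 0.0271, and adjusted p = 0.627 with an estimated correlation). Calls of lists ended without HI 2 for NF-kB (camera adjusted p = 0.0638), interferon (0.0958) and mitochondrial genes (0.0795), without naive 2 for interferon (0.534), phagocyte (0.0989) and mitochondrial genes (0.126), without naive 1 for mitochondrial genes (0.0954), and without HI 1 for neutrophil granule genes (0.0503).

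Non-classical monocytes were the class with the most calls after BAM. The chemokine receptor genes Ccr1 and Ccr2 rose, and so did Vcan, a matrix proteoglycan of monocytes. Fkbp5 and the decoy receptor Il1r2, which glucocorticoids induce, rose, as did Igfbp6, which binds insulin-like growth factors, and Ahr, the aryl hydrocarbon receptor. The glucocorticoid list did not pass as a set (camera adjusted p = 0.970), with 3 of 15 genes higher and a median log2 change of −0.12. The MHC class II genes H2-Ab1, H2-Aa and H2-Eb1, which present antigen to T cells, were low in both groups and fell. Cd83 and the antiviral interferon targets Ifit2, Ifit3 and Usp18 fell as well. edgeR called 217 of 8533 genes, 96 higher and 121 lower, from 1203460 to 2741530 UMIs per library; DESeq2 called 86, 40 higher and 46 lower, all among the 217. Markers of classical monocytes did not move together. Ccr2 (1.66) and Vcan (3.72), both on that marker list, rose, and Ly6c2 changed by −1.36 (edgeR adjusted p = 2.08e-04). Chil3 (1.48, edgeR adjusted p = 0.402) and Plac8 (−0.14, 0.436), also on it, did not pass. S100a8, abundant in neutrophils, went from 304 ± 207 to 1158 ± 888 CPM (SD, n = 2 each; log2 change 1.90, edgeR adjusted p = 0.0369).

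Vcan went from 2.76 ± 0.807 to 35.2 ± 7.43 CPM (SD, n = 2 each; log2 change 3.72, SE 0.34, edgeR adjusted p = 4.45e-05). Ccr2 went from 86.8 ± 6.70 to 278 ± 2.39 CPM (log2 change 1.66, edgeR adjusted p = 2.31e-06) and Ccr1 from 19.2 ± 8.38 to 91.5 ± 50.7 CPM (2.25). Igfbp6 went from 1.65 ± 0.763 to 34.0 ± 22.3 CPM (4.34, edgeR adjusted p = 5.36e-04) and Fkbp5 from 2.03 ± 1.84 to 19.97 ± 0.0439 CPM (3.43, adjusted p = 8.10e-04). B3gnt7 rose by 3.59, Soat2 by 3.49, Il1r2 by 3.35, Ahr by 3.14, Gpr146 by 2.22 and F13a1 by 2.19 on the log2 scale. H2-Ab1 went from 11.9 ± 5.96 to 0.817 ± 1.15 CPM (log2 change −3.31, SE 0.67, edgeR adjusted p = 0.0175), and Cd83 from 89.1 ± 15.4 to 33.3 ± 10.7 CPM (−1.38, adjusted p = 0.00176). H2-Ab1 had 50 UMIs over 719 naive cells and 4 over 569 HI cells, H2-Aa 57 and 5, and H2-Eb1 34 and 4. Counts this low can come from few cells, and a change within the monocytes was not separated from that. H2-Aa changed by −3.20, H2-Eb1 by −2.74, Lyz1 by −2.72, Nlrc5, a regulator of MHC genes, by −2.69, Cdc14b by −1.65, Angptl2 by −1.63 and Rnf144a by −1.44. Of the 24 genes named by the fixed rule, the call ended for 12 without naive 1 and 7 without naive 2, and for 5 of 21 without HI 2. Without naive 1 the calls of H2-Ab1 (−2.79, edgeR adjusted p = 0.171), H2-Aa (−2.33, 0.231), H2-Eb1 (−2.72, 0.203), Il1r2 (3.04, 0.0950) and Ahr (2.68, 0.0878) ended, and without naive 2 those of H2-Eb1 (−2.79, 0.153) and B3gnt7 (2.71, 0.0614). The count of calls was 85 without naive 1, 410 without HI 1, 179 without naive 2 and 220 without HI 2.

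**Figure D2:**
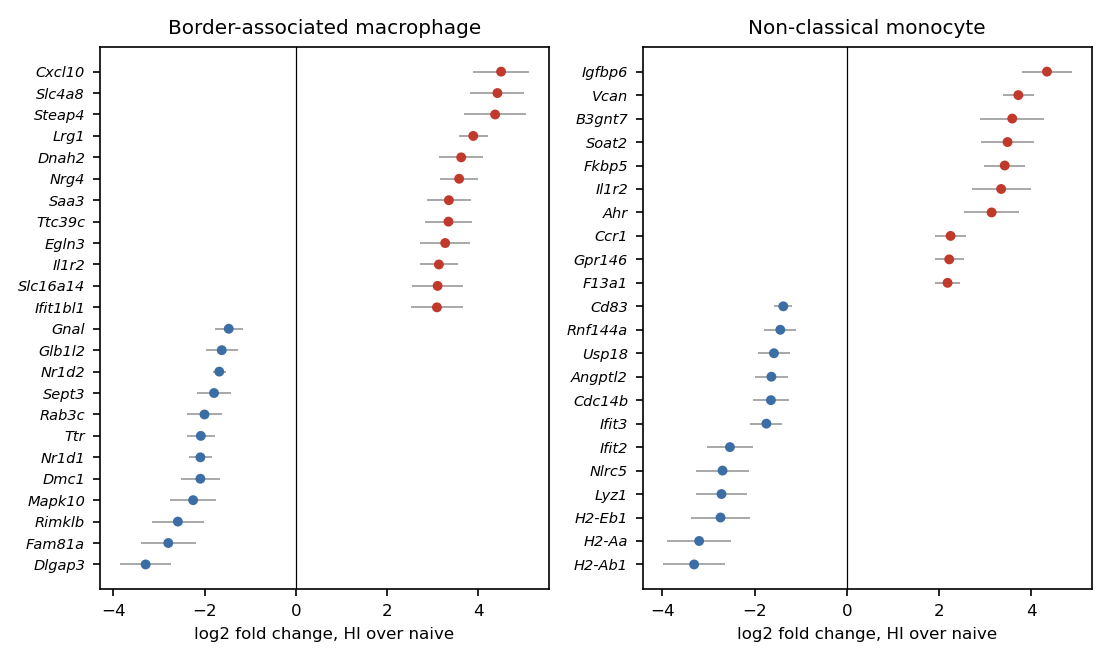
Log2 change from naive to HI (points) with its standard error (bars) for genes named by the fixed rule, 24 in BAM and 22 of 24 in non-classical monocytes. The other 2 are not reported here. In BAM Lrg1 stands at 3.89 and Nr1d2 at −1.68; in non-classical monocytes Vcan stands at 3.72 and H2-Ab1 at −3.31.

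Interferon genes had the smallest list p in non-classical monocytes. Of 23 measured, 0 rose and 9 fell, 14 adjusted over the list alone (camera adjusted p = 1.03e-14, and adjusted p = 0.627 with an estimated correlation). Ifit2 went from 9.64 ± 0.294 to 1.86 ± 0.897 CPM (SD, n = 2 each; log2 change −2.53, SE 0.50, edgeR adjusted p = 0.0134), Ifit3 from 16.0 ± 3.74 to 4.94 ± 0.0612 CPM (−1.74) and Usp18 from 12.9 ± 0.261 to 4.32 ± 0.238 CPM (−1.58). Oasl2 changed by −1.03, Ifi27l2a by −0.63, Isg15 by −0.87, Bst2 by −0.66 and Cmpk2 by −1.24. Without naive 2 the call of Ifit3 ended (−1.44, edgeR adjusted p = 0.178), and those of Ifit2 and Usp18 ended without naive 1 (−2.56, 0.0858 and −1.60, 0.125), naive 2 (−2.48, 0.101 and −1.55, 0.162) and HI 2 (−1.98, 0.175 and −1.68, 0.120). Of 7 MHC class II genes 4 fell, also adjusted over the list alone (camera adjusted p = 4.64e-05, and adjusted p = 0.627 with an estimated correlation), with Cd74 going from 521 ± 49.1 to 268 ± 24.6 CPM (log2 change −0.98). Of 16 phagocyte and lipid genes 1 rose, Fabp5 (0.60), and 3 fell, Trem2 (−0.82), Lpl (−1.13) and Axl (−1.24), against 1 and 6 adjusted over the list alone (camera adjusted p = 0.00405, and adjusted p = 0.627 with an estimated correlation). The 13 mitochondrial genes shifted down with 0 called and 3 adjusted over the list alone (camera adjusted p = 8.60e-06, and adjusted p = 0.627 with an estimated correlation). Of 21 hypoxia genes Ddit4 rose (0.80), 2 adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.627 with an estimated correlation). Of 18 oxidative stress genes Hmox1 fell (−0.48), 2 adjusted over the list alone (camera adjusted p = 0.0250, and adjusted p = 0.627 with an estimated correlation). The adhesion and migration list did not pass as a set (camera adjusted p = 0.298), with 4 of 17 genes higher, and adjusted over the list alone 4 higher and 4 lower. Without HI 2 the calls of hypoxia (camera adjusted p = 0.0515) and oxidative stress (0.0539) ended, without naive 2 those of oxidative stress (0.201) and phagocyte genes (0.0641), and without HI 1 that of oxidative stress (0.0728).

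In classical monocytes, the neutrophil-attracting chemokines Cxcl2 and Cxcl3 and the prostaglandin synthase Ptgs2 appeared almost from nothing. The cytokines Il1b and Osm and the chemokines Ccl3 and Ccl4 rose, with Socs3. Top2a and Ccna2, genes of dividing cells, rose, while the sphingosine receptor S1pr5 and the protease inhibitor Serpinb2 fell. The class held 52 to 87 cells per library, and changes within cells were not separated from a shift in which cells it holds. edgeR called 60 of 6819 genes, 58 higher and 2 lower, from 585877 to 947580 UMIs per library; DESeq2 called 68, with 50 shared. Cxcl2 had 0 UMIs in naive and 1280 in HI, at least 418-fold higher over the summed groups, and reached 820 ± 32.7 CPM (SD, n = 2; edgeR adjusted p = 1.15e-04). Cxcl3 had 1 and 541 UMIs, a ratio of 530 (Clopper-Pearson interval 94.7 to 20972), Ptgs2 0 and 92, at least 30.04-fold higher, and the adhesion gene Flrt3 0 and 65, at least 21.2-fold higher. Of 22 NF-kB genes 8 rose, 14 adjusted over the list alone (camera adjusted p = 5.49e-18, and adjusted p = 0.627 with an estimated correlation): Socs3 went from 15.3 ± 2.28 to 442 ± 165 CPM (SD, n = 2 each; log2 change 4.83), Ccl3 from 17.2 ± 2.57 to 355 ± 121 CPM (4.35), Ccl4 from 3.69 ± 5.22 to 580 ± 245 CPM (6.98) and Il1b from 50.1 ± 11.2 to 1389 ± 1016 CPM (4.83), and Osm rose by 4.51. Of 22 cell cycle genes 6 rose, 18 adjusted over the list alone (camera adjusted p = 5.49e-18, and adjusted p = 0.627 with an estimated correlation), with Top2a going from 5.32 ± 4.54 to 92.7 ± 12.0 CPM (log2 change 4.29), Ccna2 at 4.22 and Cenpa at 1.76. S1pr5 went from 50.04 ± 18.5 to 4.94 ± 3.07 CPM (−3.20, edgeR adjusted p = 0.0420) and Serpinb2 changed by −1.78. Without HI 1 there were 15 calls and those of Ptgs2 (edgeR adjusted p = 0.157), Flrt3 (0.272), S1pr5 (−2.72, 0.338) and Serpinb2 (−1.65, 0.365) ended; without naive 1, naive 2 and HI 2 there were 275, 125 and 180 calls.

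Further lists of classical monocytes passed with the preset correlation only. Of 23 interferon genes 0 passed and 8 fell adjusted over the list alone (camera adjusted p = 9.51e-11, and adjusted p = 0.627 with an estimated correlation). Of 21 immediate-early genes 4 rose, among them Ier3 (3.93), Egr1 (1.75) and Junb (1.02), against 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.627 with an estimated correlation). Of 14 unfolded protein response genes Hspa5 rose (1.09), 7 adjusted over the list alone (camera adjusted p = 9.29e-07, and adjusted p = 0.627 with an estimated correlation). Of 21 hypoxia genes the lipid droplet gene Hilpda rose, from 4.67 ± 0.636 to 143 ± 36.6 CPM (SD, n = 2 each; log2 change 4.93), 2 adjusted over the list alone (camera adjusted p = 7.66e-05, and adjusted p = 0.683 with an estimated correlation). Without HI 1 this list's call ended (camera adjusted p = 0.0600). Of 12 glucocorticoid response genes Il1r2 rose (4.55), and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.00816, and adjusted p = 0.627 with an estimated correlation). Of 9 neutrophil granule genes 2 rose, S100a9, from 379 ± 62.0 to 2740 ± 18.0 CPM (log2 change 2.87), and Lcn2 (3.17), against 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.87e-04, and adjusted p = 0.627 with an estimated correlation). Retnlg, abundant in the neutrophil cluster at 16277 to 21623 CPM, stood at 0 in 3 libraries and 1.19 CPM in HI 2 among classical monocytes.

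Few single genes passed in microglia-like cells, though 834 were higher and 759 lower at an edgeR unadjusted p under 0.05. Socs3 and the chemokines Ccl5 and Ccl12 rose, as did the metal transporter Slc39a14 and Igfbp6. The immediate-early transcription factor Fos and the phosphatase Dusp1, both switched on within minutes of stimulation, fell. edgeR called 8 of 10964 genes, 6 higher and 2 lower, from 7392220 to 9599930 UMIs per library; DESeq2 called 80, 45 higher and 35 lower, with 4 shared. Socs3 went from 11.3 ± 1.66 to 56.4 ± 19.8 CPM (SD, n = 2 each; log2 change 2.29, SE 0.25, edgeR adjusted p = 0.0269), Ccl12 from 96.4 ± 3.93 to 247 ± 39.1 CPM (1.34, adjusted p = 0.00947) and Slc39a14 from 4.36 ± 0.614 to 14.97 ± 1.499 CPM (1.75). Ccl5 went from 0.635 ± 0.133 to 5.04 ± 0.339 CPM (2.92) and Igfbp6 from 0.994 ± 0.0670 to 6.01 ± 0.652 CPM (2.56). Fos went from 44.5 ± 6.72 to 12.6 ± 0.892 CPM (log2 change −1.84, edgeR adjusted p = 0.00947) and Dusp1 from 18.1 ± 0.676 to 5.46 ± 0.585 CPM (−1.74, adjusted p = 0.0131). The call of Ccl5 ended without naive 1 (3.17, edgeR adjusted p = 0.153) and without naive 2 (2.75, 0.188), that of Igfbp6 without naive 1 (2.64, 0.153) and naive 2 (2.50, 0.188), and that of Slc39a14 without naive 2 (1.63, 0.0724); 372 genes passed without HI 1 and 1164 without HI 2.

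As sets, the homeostatic genes of microglia shifted down. Of 20 measured 0 passed over all genes and 9 fell adjusted over the list alone (camera adjusted p = 3.54e-09, and adjusted p = 0.627 with an estimated correlation), with the purine receptor P2ry12 at −0.61, Gpr34 at −0.36 (edgeR adjusted p = 0.126) and Cst3 at −0.20. Of 21 NF-kB genes 2 rose, 4 adjusted over the list alone (camera adjusted p = 0.00367, and adjusted p = 0.627 with an estimated correlation). Of 22 immediate-early genes 2 fell, and adjusted over the list alone 3 rose and 7 fell (camera adjusted p = 0.0230, and adjusted p = 0.627 with an estimated correlation). The 17 unfolded protein response genes shifted up with 0 called, also adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.627 with an estimated correlation). The 20 interferon genes shifted down with 0 called, also adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.683 with an estimated correlation). The 22 hypoxia genes shifted up with 0 called, and adjusted over the list alone Ldha rose (0.51) and Egln3 fell (−1.11) (camera adjusted p = 0.0336, and adjusted p = 0.918 with an estimated correlation). The 19 phagocyte and lipid genes shifted down with 0 called and 2 adjusted over the list alone (camera adjusted p = 0.0372, and adjusted p = 0.918 with an estimated correlation). Without HI 1 the calls of hypoxia (camera adjusted p = 0.643), NF-kB (0.599) and interferon (0.221) ended, without naive 2 that of hypoxia (0.996), without HI 2 that of immediate-early genes (0.160), and without naive 1 that of phagocyte genes (0.592), which without HI 2 passed in the other direction (0.0466).

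Cluster 17, which shares markers of BAM and microglia and joins the classical monocyte class at resolution 0.8, raised Spp1, Socs3, the adhesion molecule Vcam1 and the cytokine Tnf. It lowered Ttr, the growth factor gene Gdf3, the phosphodiesterase Pde4b and the GTPase Rhob. edgeR called 28 of 6808 genes, 21 higher and 7 lower, from 591753 to 1213910 UMIs per library; DESeq2 called 21, 18 higher and 3 lower, with 19 shared. Spp1 went from 222 ± 58.5 to 1722 ± 1177 CPM (SD, n = 2 each; log2 change 2.91, SE 0.31, edgeR adjusted p = 1.15e-04), Socs3 from 13.4 ± 2.60 to 81.1 ± 17.7 CPM (2.64), Vcam1 from 28.0 ± 3.45 to 112 ± 65.0 CPM (2.05) and Tnf from 25.9 ± 4.00 to 76.7 ± 50.4 CPM (1.63). Ttr went from 141 ± 123 to 5.38 ± 0.641 CPM (log2 change −4.82, edgeR adjusted p = 9.31e-04) and Gdf3 from 42.5 ± 2.78 to 6.39 ± 4.91 CPM (−2.77), with Pde4b at −1.24 and Rhob at −0.91. Of 14 NF-kB genes 4 rose, among them Ccl2 (1.24) and Ccl12 (0.84), 7 adjusted over the list alone (camera adjusted p = 1.57e-06, and adjusted p = 0.627 with an estimated correlation). Of 13 unfolded protein response genes Psat1 rose (1.49), 7 adjusted over the list alone (camera adjusted p = 1.96e-06, and adjusted p = 0.627 with an estimated correlation). Of 15 phagocyte and lipid genes 2 rose, Spp1 and Abcg1 (1.1), against 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.627 with an estimated correlation). The 18 hypoxia genes shifted up with 0 called, also adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.627 with an estimated correlation), and the 18 immediate-early genes shifted down with 0 called, 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.627 with an estimated correlation). The 19 interferon genes shifted up with 0 called, also adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.918 with an estimated correlation), and of 18 microglia homeostatic genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.0372, and adjusted p = 0.683 with an estimated correlation). Without HI 1 the calls of Tnf (0.74, edgeR adjusted p = 0.722), Pde4b (−0.94, 0.192), interferon (camera adjusted p = 0.987) and microglia homeostatic genes (0.342) ended, without naive 1 those of Tnf (1.43, 0.0980) and microglia homeostatic genes (0.192), and without naive 2 those of Rhob (−0.73, 0.0733) and interferon (0.534). Calls numbered 77 without HI 1, 47 without naive 2 and 108 without HI 2.

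In cluster 21, the Cd209a and H2-Eb1 cells, edgeR called 0 of 6529 genes, with 119 higher and 130 lower at an unadjusted p under 0.05, from 569014 to 857888 UMIs per library; DESeq2 called 1. Without naive 1, HI 1 and HI 2 there were 2, 67 and 118 calls. The 20 hypoxia genes shifted up (camera adjusted p = 0.0291, and adjusted p = 0.627 with an estimated correlation) and the 17 interferon genes shifted down (camera adjusted p = 0.00176, and adjusted p = 0.627 with an estimated correlation). The 18 BAM homeostatic genes shifted down (camera adjusted p = 0.00530, and adjusted p = 0.627 with an estimated correlation), and adjusted over the lists alone 1 gene, of this list, fell. The hypoxia call ended without naive 1 (camera adjusted p = 0.123) and without HI 1 (0.130), and that of BAM homeostatic genes without HI 1 (0.184) and without naive 2 (0.233), and 6, 5 and 10 lists passed without HI 1, naive 2 and HI 2.

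Summed over all cells of a library, Lrg1, Prok2 and Cxcl2 rose, and Fabp7, Sostdc1 and Pcp4l1 fell. Of these only Lrg1 passed without any single library. Gene lists were not tested on these sums. Prok2 and Lrg1 are leading genes of the neutrophil cluster, Sostdc1 and Pcp4l1 of cluster 35 and Fabp7 of cluster 9; shifts in cell shares and changes within classes were not separated in these sums. edgeR called 94 of 14702 genes, 66 higher and 28 lower, from 49598000 to 63422600 UMIs per library; DESeq2 called 744, 445 higher and 299 lower, and all 94 were among them. Lrg1 went from 2.67 ± 0.169 to 44.4 ± 1.51 CPM (SD, n = 2 each; log2 change 4.09, SE 0.07, edgeR adjusted p = 2.79e-04), Prok2 from 0.674 ± 0.00377 to 13.02 ± 2.34 CPM (4.31) and Cxcl2 from 2.16 ± 0.553 to 43.3 ± 20.5 CPM (4.36), and Steap4 rose by 4.00. The lipase gene Lipg had 2 UMIs in naive and 116 in HI, a ratio of 61.0 (Clopper-Pearson interval 16.5 to 509). Fabp7 went from 76.5 ± 3.41 to 26.0 ± 4.94 CPM (log2 change −1.51, edgeR adjusted p = 0.0328) and Sostdc1 from 1.39 ± 0.0741 to 0.0719 ± 0.0124 CPM (−4.21, adjusted p = 0.0245), with Gpr37l1 at −2.69, Pcp4l1 at −1.97 and Nr1d2 at −1.62. Of the 10 genes named by the fixed rule 9 ended without naive 1, 9 without naive 2, 2 without HI 1 (Lipg, edgeR adjusted p = 0.0717, and Gpr37l1, 0.0773) and 1 without HI 2 (Gpr37l1, 0.0550). The calls numbered 2 without naive 1, 3 without naive 2, 142 without HI 1 and 316 without HI 2, and that of Fabp7 ended without naive 1 (−1.47, edgeR adjusted p = 0.188) and without naive 2 (−1.55, 0.121).

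Whether classes answered HI differently was tested as an interaction between class and HI. The MHC class II chaperone gene Cd74 and the interferon target Isg15 changed downwards in non-classical monocytes relative to BAM, and the chemokine receptor genes Ccr1 and Ccr2 upwards. BAM gained Spp1, Fkbp5 and the oxygen sensor Egln3 more than microglia did. edgeR called 354 of 12560 genes between BAM and non-classical monocytes, 130 with a higher change in the monocytes and 224 with a lower one. Ccr1 changed by −0.08 in BAM and 2.25 in non-classical monocytes (difference 2.36, edgeR adjusted p = 4.95e-51), Ccr2 by 0.34 and 1.66 (1.35, 6.53e-05), Cd74 by 0.33 and −0.98 (−1.26, 5.87e-49) and Socs3 by 3.02 and 0.70 (−2.32, 5.09e-33). The test within non-classical monocytes alone gave Ccr1 an edgeR adjusted p of 0.00215. The much smaller p-values between BAM and non-classical monocytes rest on spread pooled over genes more than on each gene's own spread between libraries. As sets, in tests added after seeing the data, interferon genes differed between this pair (camera adjusted p = 2.96e-12, and adjusted p = 0.759 with an estimated correlation), as did MHC class II genes (camera adjusted p = 0.0497, and adjusted p = 0.766 with an estimated correlation), while the adhesion and migration list did not pass (camera adjusted p = 0.244). Cd33, Smpdl3b, Isg15 and Ifi205 were called in opposite directions in the pair of classes: Isg15 changed by 0.40 in BAM and −0.87 in non-classical monocytes (difference −1.27, edgeR adjusted p = 8.84e-13). Between BAM and microglia 50 of 12777 genes differed, among them Spp1 (2.38 in BAM and 0.21 in microglia, difference −2.20, edgeR adjusted p = 1.70e-06), Fkbp5 (2.02 and −0.27, −2.30, 0.00682) and Egln3 (3.27 and −1.11, −4.27, 0.0111). Microglia and non-classical monocytes differed in 61 genes, non-classical monocytes and cluster 17 in 80, BAM and cluster 17 in 33, and microglia and cluster 17 in 6. Between BAM and microglia 1 gene passed without naive 1, 199 without HI 1, 4 without naive 2 and 121 without HI 2. Between BAM and non-classical monocytes the counts were 207 without naive 1, 132 without naive 2 and 182 without HI 2, and between microglia and non-classical monocytes 20, 31 and 192, with 208 without HI 1. Between BAM and cluster 17 the counts were 18 without naive 1 and 18 without naive 2, between non-classical monocytes and cluster 17 they were 43 without naive 2 and 35 without HI 1, and between microglia and cluster 17 the 6 became 10, 53, 19 and 69 without naive 1, HI 1, naive 2 and HI 2.

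**Figure D3:**
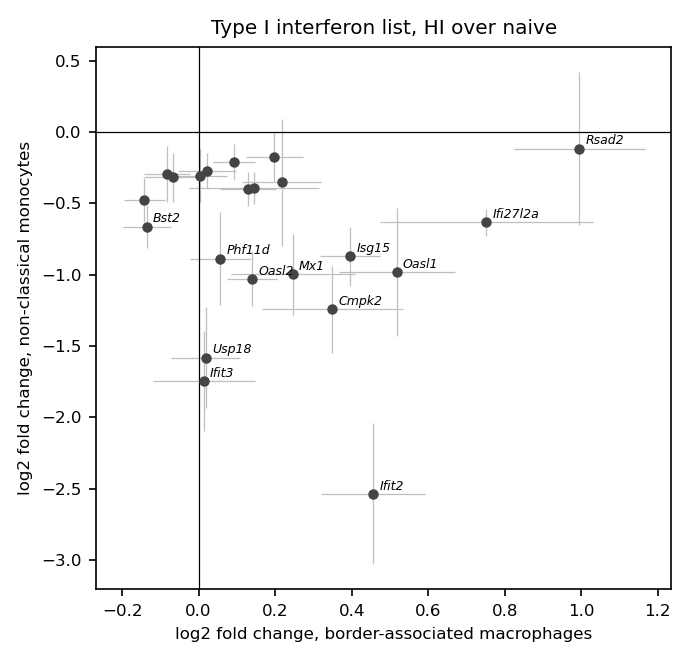
Log2 change from naive to HI of 22 of the 23 interferon genes measured in both classes, in BAM (horizontal axis) and non-classical monocytes (vertical axis), with standard errors as bars; genes below −0.5 vertically or above 0.5 horizontally are named. The other gene is not reported here. Isg15 stands at 0.40 in BAM and −0.87 in non-classical monocytes.

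The receptor libraries were read on the same cells. B-lineage cells of the neonatal meninges carried unswitched receptors. A productive heavy chain, the larger part of the antibody receptor, was found in 72, 28, 84 and 70 kept cells of naive 1, HI 1, naive 2 and HI 2, and in 92.3%, 96.4%, 91.3% and 94.6% of B-lineage cells (Clopper-Pearson intervals 84.0 to 97.1, 81.7 to 99.9, 83.6 to 96.2 and 86.7 to 98.5). Every B cell had a light chain. Of pre-B cells, 72.7% of naive 1, 75.8% of naive 2 and 78.9% of HI 2 had a heavy chain, and 31.8%, 15.2% and 10.5% a light chain. IGHM, the constant gene of IgM, was the heavy chain gene in 97.2% of naive 1 and 100% of the other libraries, and 0 cells had a switched class, which allows up to 4.17%, 10.7%, 3.57% and 4.29%. Lambda light chains were 9.52% in naive 1, 3.12% in naive 2 and 5.26% in HI 2, with 0 of 29 in HI 1, which allows up to 10.3%. Cells in clones of at least 2 cells were 0 of 72, 4 of 28 (14.3%, interval 4.03 to 32.7), 2 of 84 (2.38%, 0.290 to 8.34) and 2 of 70 (2.86%, 0.348 to 9.94), and the 4 cells of HI 1 made up 1 clone. The third complementarity region of the heavy chain had a median of 12, 10.5, 12 and 12 residues. Receptor shares are given per library and were not compared between HI and naive by a test.

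T-cell receptors were rarer. In cluster 25 a beta chain was found in 30 of 49 cells of naive 1 (61.2%, Clopper-Pearson interval 46.2 to 74.8), 24 of 26 of HI 1 (92.3%, 74.9 to 99.1), 19 of 41 of naive 2 (46.3%, 30.7 to 62.6) and 25 of 38 of HI 2 (65.8%, 48.6 to 80.4). Cluster 29, with gamma chain genes, had a beta chain in 0 of 19, 13, 21 and 27 cells. Of 26 cells with a beta chain in HI 1, 24 were of cluster 25. Clones of at least 2 cells held 2 of the 26 (7.69%, interval 0.946 to 25.1) and 0 in the other libraries, which allows up to 10% of 30 cells in naive 1, 15.8% of 19 in naive 2 and 12% of 25 in HI 2. The most used beta variable gene was TRBV19 in naive 1, HI 1 and HI 2 (23.3%, 26.9% and 16.0%) and TRBV31 in naive 2 (26.3%). The median length of the third complementarity region of the beta chain was 13 residues. No receptor sequence (the third complementarity region with its V and J genes) was found in more than 1 library, out of 254 distinct heavy chains and 105 distinct beta chains, those of single cells included. As a background, 0 of 2983, 2896, 3796 and 4456 BAM of naive 1, HI 1, naive 2 and HI 2 had a heavy or beta chain, which allows up to 0.101%, 0.104%, 0.0790% and 0.0673%.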

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

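The tests of glucocorticoid targets, microglia shares, UMI ratios, Fabp7 in other classes and Ly6c2, and the list test of the difference between classes, were chosen only after the result was seen; the tests of the other clock genes and of each library left out were not.

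These results stand out because the effect of HI differed between classes by a test of the difference itself. The very small p-values of that test rest on spread pooled over genes more than on each gene's own spread between libraries. edgeR called 50 genes between BAM and microglia, 354 between BAM and non-classical monocytes, 33 between BAM and cluster 17, 61 between microglia and non-classical monocytes, 6 between microglia and cluster 17 and 80 between non-classical monocytes and cluster 17. Between BAM and non-classical monocytes 4 genes were called in opposite directions. Cd33, a sialic acid receptor, changed by −0.41 and 1.53 (difference 1.93, edgeR adjusted p = 1.28e-23), Smpdl3b by 0.75 and −0.77 (−1.48, 1.38e-23), Isg15 by 0.40 and −0.87 (−1.27, 8.84e-13) and Ifi205 by 1.85 and −1.06 (−2.90, 3.85e-06). The interferon list as a set differed between BAM and non-classical monocytes with a camera adjusted p of 2.96e-12, and 0.759 with an estimated correlation.

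Lower Nr1d1 and Nr1d2 after HI may reflect different hours of the day at collection or a response of the cells. Of 10 other clock genes in BAM 9 moved in the direction that a shift of the clock gives, with Dbp (−0.85), Arntl (0.37) and Cry1 (1.06) called, but the median signed change was 0.203, between the bounds set for and against a shift. A glucocorticoid-type response would raise Fkbp5 where Nr1d2 falls: Fkbp5 rose by 2.02 in BAM, while in microglia Nr1d2 stood at −1.73 (edgeR adjusted p = 0.0620) with Fkbp5 at −0.27. The pair of explanations cannot be told apart, since the hour of collection is not given in the sources used here and neither bound was passed. HI itself, with any surgery or handling that came with it, stays open as a cause, untested apart from these.

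Fewer macrophages with neuronal RNA after HI (cluster 9) may follow from tissue handling or from the cells. Less brain tissue in the HI preparations is argued against by microglia only as far as such tissue yields microglia, whose share in HI was 1.01 of that in naive libraries. That share cannot speak for other tissue carried along, which stays open. Cluster 35, with choroid plexus genes, went from 33 naive cells to 1 HI cell, and Ttr changed by −4.82 in cluster 17. Doublets are argued against by cluster 9 cells holding 0.945 of the UMIs of BAM (0.875 to 0.965 over libraries). Free RNA at a higher level in the naive suspensions stays open: Fabp7 changed by −1.18 in microglia and −1.57 in non-classical monocytes (edgeR adjusted p of 0.0620 and 0.284), beside −1.09 in BAM, while Stmn2 changed by −0.17 in microglia and −1.02 in BAM. The test set first, before its values were seen, was the sum over the neuronal and glial list in microglia and both monocyte classes, and its mean change of −0.0682 (−0.299 to 0.255) spoke against free RNA by the bounds then set, but most of these UMIs are of Tuba1a, which those classes hold in both groups, so it was set aside, and a later test, on genes that define cluster 9, was dropped. RNA taken up by the cells or sticking to them in clumps, and a change in uptake after HI, stay open too.

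Lower interferon genes in non-classical monocytes after HI may be a change of these cells or of which cells the class holds. The shift was not particular to this class, where the median log2 change of the list was −0.63. The median was −0.96 in classical monocytes, −0.28 in microglia and −0.23 in cluster 21, but 0.11 in BAM and 0.29 in cluster 17. Whether these classes share a cause was not tested. Admixture of classical monocytes is argued against by Ly6c2, which changed by −1.36. Ccr2 (1.66) and Vcan (3.72), on the same marker list, rose, so the list does not speak with 1 voice. A single library did not set the list's call, whose largest adjusted p by camera without 1 library was 1.52e-08, with the preset correlation. A different mix of non-classical subsets in the blood after HI stays open, as does a biological fall within cells.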

How the results depend on the processing

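The tests with clusters 9, 17 and 35 added to BAM were chosen only after the result was seen; the others were not. Where a library is left out, the lone library of its group is assumed to vary like the other group. No gene called in any class changed sign under any alternative run for genes.

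Counts of called genes moved under these settings. With no filter on low counts they were 1912 in BAM, 679 in microglia, 394 in non-classical monocytes, 93 in cluster 17, 497 in classical monocytes, 47 in cluster 21 and 282 over all cells. With DESeq2 they were 80 in microglia, 86 in non-classical monocytes, 1 in cluster 21 and 744 over all cells. With doublets kept they were 29 in microglia, 18 in cluster 17 and 109 in classical monocytes, and at resolution 0.8 there were 120 in classical monocytes, a class that then also holds the cells of cluster 17. With each library left out they ranged from 105 to 1800 in BAM, 6 to 1164 in microglia, 85 to 410 in non-classical monocytes, 36 to 108 in cluster 17, 15 to 275 in classical monocytes, 0 to 118 in cluster 21 and 2 to 316 over all cells. BAM with clusters 9, 17 and 35 gave 616 calls, 475 of them among the 655. The cause of these shifts was not tested.

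The replicate number as a block gave 1613 calls in BAM, 815 in microglia, 132 in cluster 17, 320 in classical monocytes, 1 in cluster 21 and 216 over all cells. The labels do not say that a number marks a run, and with 2 pairs the residual correlations of same-numbered libraries (−0.01 to 0.28) do not show it, so these values are given only as a setting, and a call lost here is no weaker effect. Under this block 6 lists passed in cluster 21 and 0 classes in shares (cluster 35 −4.65, cluster 9 −2.94, mature neutrophils 1.84).

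Of 78 named genes 76 passed with RLE size factors, 78 with no filter, 71 with doublets kept and 76 with the block, 39 of 50 with DESeq2, 64 of 68 with the stricter cell filter, 58 of 60 at resolution 0.8 and 18 of 24 with clusters 9, 17 and 35. Without naive 1 and naive 2 there were 41 and 42 of 78, without HI 1 there were 68 of 78 and without HI 2 there were 66 of 75.

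Of class shares, TMM over classes called 0 (cluster 35 −4.52, cluster 9 −2.71, mature neutrophils 1.90, edgeR adjusted p of 0.0910, 0.0607 and 0.181), and the stricter cell filter left mature neutrophils at 1.79 (edgeR adjusted p = 0.0556). With each library left out 0 to 6 classes passed, with cluster 35 from −7.12 to −3.53, cluster 9 from −3.42 to −2.51 and mature neutrophils from 1.44 to 2.31. Changes that did not pass with all libraries turned sign: cluster 29 with doublets kept (−0.14) and group 2 innate lymphoid cells with doublets kept (0.072) and TMM (0.17). The same happened with a library left out for cluster 29 (−0.24 to 0.23), group 2 innate lymphoid cells (−0.45 to 0.48), microglia (−0.23 to 0.32), classical monocytes (−0.51 to 0.054), cluster 17 (−0.77 to 0.42) and immature neutrophils (−1.28 to 2.39).

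Gene lists passed in 0 cases in each class with an estimated correlation and 0 with fry, against 12, 7, 6, 7, 8 and 3 with the preset one in BAM, microglia, non-classical monocytes, cluster 17, classical monocytes and cluster 21. With each library left out the counts were 9 to 13, 8 to 10, 6 to 9, 6 to 8, 9 to 10 and 3 to 10. The camera adjusted p of phagocyte lipid and disease-associated genes, microglia, was 0.0466 for a rise without HI 2, and 8.63e-17 to 0.592 over the libraries left out.

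Differences of the HI effect numbered 420 (BAM and microglia), 166 (microglia and non-classical monocytes) and 48 (microglia and cluster 17) with no filter on low counts, and 40 with RLE size factors (microglia and non-classical monocytes). With each library left out they ranged from 1 to 199 (BAM and microglia), 132 to 266 (BAM and non-classical monocytes), 18 to 49 (BAM and cluster 17), 20 to 208 (microglia and non-classical monocytes), 10 to 69 (microglia and cluster 17) and 35 to 64 (non-classical monocytes and cluster 17).

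With all productive contigs of the receptor libraries, cells in B-cell clones were 9% in naive 2 and 12.9% in HI 2, and cells in T-cell clones were 13.8% in HI 1 and 8% in naive 2. What the tests can show differs between the smallest classes. In simulated data, a best case, 25.5% of 2-fold changes were recovered in cluster 21, 31.6% in classical monocytes and 66.3% in cluster 17. The cause was not tested.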

Other observations

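The tests of neutrophil levels and the genes named here were chosen only after the result was seen. Beyond the genes above, BAM raised Gja1, the gap junction protein connexin, from 7.12 ± 0.951 to 23.0 ± 0.539 CPM (SD, n = 2 each; log2 change 1.70, edgeR adjusted p = 9.67e-04), and Hif3a, a hypoxia-inducible factor that damps the others, from 8.02 ± 1.77 to 37.2 ± 8.40 CPM (2.22, adjusted p = 0.00173). Map3k6 (1.87) and Pik3ip1 (2.13), genes of the glucocorticoid list, rose with them. S1pr1, the receptor that guides cells along sphingosine phosphate, fell (−0.56), as did Bbc3, which promotes cell death (−0.78). The leukotriene enzyme Alox5 (0.64), the granule proteoglycan Srgn (0.95), the complement receptor C5ar1 (0.42) and the adhesion receptor Cd44 (0.42) rose. Fos (−0.54) and Ier2 (−0.38), immediate-early genes, fell.

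Chemokine RNA was also read in neutrophils, where it was not tested. Cxcl2 stood at 538 and 5.52 CPM in mature neutrophils of naive 1 and naive 2 and at 3202 and 981 CPM in those of HI 1 and HI 2; Ccl4 stood at 0 in both naive libraries and at 725 and 431 CPM. Among classical monocytes, Cxcl2 was 0 in both naive libraries and 843 and 796 CPM in HI 1 and HI 2. With 19 mature neutrophils in naive 1, this class was under the 40 cells needed for a test of genes.

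In the receptor libraries of HI 1, 1 heavy chain lay in a barcode of an immature neutrophil and 1 beta chain in a barcode of a microglia-like cell. In cluster 32 a beta chain was found in 0 of 22, 1 of 9, 0 of 22 and 0 of 11 cells of naive 1, HI 1, naive 2 and HI 2. IGHV5-6 was the most used heavy chain variable gene of HI 1 (17.9%).

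Several lists that did not pass had a median or mean of the other sign than their test. BAM homeostatic genes in BAM had a median log2 change of −0.02 and a mean of 0.02, cell cycle genes in cluster 21 had a median of 0.40 and a mean of 0.19 with a test in the other direction (camera adjusted p = 0.0783), and microglia homeostatic genes in non-classical monocytes a median of −0.15 and a mean of 0.06.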
